A study of Mus musculus with 3 samples.

How the data were processed

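mRNA was counted in single cells of 3 treated G-Smo mouse tumours by Drop-seq, after papain dissociation, per the labels' protocols. The deposited tables hold counts of unique molecular identifiers (UMIs) per gene and barcode, and no normalisation by the authors is recorded for them. Per the submitters' processing notes, STAR and Cell Ranger were used, with no version or role given, and the build is named as GRCh38. However, 18566 of 19744 gene symbols (94.03%), with 96.4% of counts, matched mouse gene names, so no coordinates were used. Every deposited barcode holds at least 50 genes, which shows a filter before deposit. The untreated control tumours are not analysed here, so no comparison of treated with untreated tumours was made. No cell annotation was used, so classes were rebuilt from the counts and can differ from those of the study. The 3 tumours differed by more than sampling noise (chi-square per degree of freedom 8.06 between tumours 1 and 2, 5.35 between 1 and 3, and 5.60 between 2 and 3), so none was a duplicate.

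Cells were kept with at least 500 UMIs and 200 genes, at most 10% mitochondrial UMIs, and a UMI total within 4 SD of the tumour's median. Doublets called by Scrublet at an expected rate of 6% were removed. This left 267, 5 and 156 cells in tumours 1, 2 and 3, after 37, 3 and 15 were over the mitochondrial limit and 4, 0 and 11 were called doublets. Scrublet was run only in tumours with at least 30 cells, so the 5 cells of tumour 2 were not screened. Counts were normalised to 10000, and 2000 variable genes chosen within tumours, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9). Cycle and drug genes were left out of clustering. Log values were clustered unscaled, with variable genes from Pearson residuals; this was chosen after clusters from a scaled version had been seen. Clusters were named by marker lists fixed before the data were examined. Progenitor-like clusters were those left when no other type's markers stood out. Their progenitor list level had only to be not far below that of other cells, and their leading genes were mostly not markers. At 200 UMIs, 2 clusters named progenitor-like, of 104 and 48 cells, held more granule neuron than progenitor marker counts. Shares carry exact binomial intervals at the 95% level within tumours, and intervals cover counting error only.

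The planned states were cycling (at least 3 cycle UMIs of 500 thinned UMIs) and, among cells with 0, undifferentiated or differentiating by neuronal UMIs. They held 224, 3 and 136 cycling, 1, 0 and 1 undifferentiated and 5, 0 and 1 differentiating cells in tumours 1, 2 and 3. Only the cycling state of tumours 1 and 3 reached the minimum of 20 cells, so no tumour had both states of a comparison. The planned tests between states and their list tests were therefore not run. The class test of drug genes and the paired test of cycling shares needed classes of at least 20 cells in every tumour. Tumour 2 had only 5 cells in all, so these were not run either. An added design was fixed after depth and state counts had been seen and before any test. Cells of at least 200 UMIs and 100 genes were thinned to 200 UMIs, which left 942, 84 and 912 cells. Cells past the UMI and gene minimums numbered 1060, 144 and 1058, of which 97, 51 and 133 were over the mitochondrial limit and 11, 7 and 6 were called doublets. A state criterion of at least 2 against 0 cycle UMIs was also counted before sets were adopted. Lineage cells were those in lineage clusters without a marker call for another type, 784, 69 and 729 cells. A marker call needed at least 3 UMIs of at least 2 genes of a list, and these calls were added after seeing the data. Clusters kept out of the lineage as mixed held 15.4% ± 2.81 of cells (SD, n = 3). Of these 308 cells, 279 were in a cluster led by S100a8 and S100a9. Its progenitor (48.84 per 10000) and granule neuron (53.41) marker levels were like those of lineage clusters, so lineage cells were left out with it. Neutrophil markers had 47, 0 and 4 counts in the totals of tumours 1, 2 and 3, with 2, 0 and 4 in barcodes of under 200 counts. Only 1 cell, in tumour 1, was called neutrophil, so the name of this cluster can rest on very few cells. A lineage set by marker calls alone, which takes in cells of this cluster, gave 154 calls between cycle sets and 79 between neuronal sets, against 157 and 78.

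Within each tumour, lineage cells were ranked by UMIs of the S and G2/M lists, or of the neuronal state list, among their 200 thinned UMIs, with ties broken at random, and were divided into 3 sets of near-equal size, of which the highest was compared with the lowest. Each set held 261, 23 and 243 cells in tumours 1, 2 and 3. The sets are ranges of a score and not cell types. Raw counts were summed per tumour and set, 120602, 6879 and 101133 in cycle-high against 102982, 5859 and 88380 in cycle-low cells. Neuronal-high sums were 99993, 7217 and 92468, and neuronal-low sums 117419, 6224 and 92500. Sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit, glmQLFTest) with the tumour as a block and Benjamini-Hochberg adjustment over all genes tested. Both sets come from the same animal, which gives the pairing; the correlations of their deviations were 0.253, 0.068 and 0.14 for the cycle sets and 0.29, 0.154 and 0.215 for the neuronal sets. Genes of the splitting list were left out of the test. The exceptions are the neuronal genes between cycle sets and the cycle genes between neuronal sets, which were tested. The cells of the comparisons overlap, so these are not independent. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. Remaining lists with no gene called and no pass by camera in either comparison were those for glycolysis, cholesterol and lipid synthesis, p53 targets, stress and stem-like or glial genes, and for serine and 1-carbon metabolism, where 1 gene rose between cycle sets when adjusted over the list alone. Of 7 mitochondrially encoded genes 1 rose between cycle sets and 2 fell between neuronal sets.

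Named genes are the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean log2 CPM of at least 5 and the same direction in all 3 tumours. Up to 4 passing members of each list discussed and cdk_rb genes with a mean log2 CPM of at least 4 were added. In the added design the rule left out only the genes of the splitting list. Some genes that met these rules, and a leading gene of a cluster, are not reported here. The procedure was tested on simulated data. For the cycle sets, with 2088 genes tested, 45 of 95 genes changed 2-fold and 82 of 86 changed 4-fold were called, with 5 false calls. For the neuronal sets, with 2152 genes tested, 41 of 91 and 86 of 87 were called, with 0 false calls in edgeR. Alternatives were DESeq2 1.42.0, limma-voom, other normalisation, filters on genes and cells, clustering resolution, splits and depth, no replicate block, and each tumour left out. The range of total counts per tumour, 248617 to 1324350, sets the precision, and tumour 2 adds few counts to any sum.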

Results

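Single-cell mRNA counts were collected from 3 medulloblastomas, each from a separate G-Smo mouse. In these mice hGFAP-Cre switches on SmoM2, an activated form of the Hedgehog pathway gene Smo, and cerebellar granule neuron progenitors form tumours. Each mouse had received 5 daily intraperitoneal doses of palbociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, at 25 mg/kg in a polyoxazoline nanoparticle (POx-palbo). Dosing began on postnatal day 10, and the tumours were harvested on postnatal day 16. All 3 belong to 1 group, so values are compared between cells of the same tumours and not with untreated tumours, which are not analysed here. The tables held 8827, 2330 and 9802 barcodes with total counts of 1150463, 248617 and 1324350 in tumours 1, 2 and 3. Depth was low, with medians of 84, 85 and 105 counts per barcode, and 311, 9 and 184 barcodes reached 500 counts.

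Most cells deep enough to be classed fell in clusters named as tumour lineage. The progenitor name was given where no other type's markers stood out. In tumours 1 and 3 progenitor markers were little above their level in shallow barcodes. They took 0.42%, 0.11% and 0.44% of non-mitochondrial counts in barcodes of 500 or more counts of tumours 1, 2 and 3. In barcodes of 50 to 99 counts they took 0.37%, 0.38% and 0.41%. Of 428 cells with at least 500 UMIs, 404 fell in the lineage, a mean of 83.03% ± 19.97 (SD, n = 3 tumours). Tumour 2 gave only 5 of these cells, and without it the lineage share was 94.5%. Progenitor-like cells made up 62.9% ± 20.7 (SD, n = 3). Granule-neuron-like cells, led by the adhesion gene Cntn2, the differentiation factor Neurod1, the splicing regulator Celf4 and the imprinted RNA Meg3, made up 20.1% ± 6.75 (SD, n = 3). A myeloid-like cluster of 11 cells was led by the lipid carrier Apoe, the lysosomal proteases Ctsd, Ctss and Ctsb, and the complement genes C1qa, C1qb and C1qc. A further 13 cells mixed astrocytic (Slc4a4) with endothelial and mural genes (Cldn5, Rgs5) and were not split.

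The study asked which tumour cells stay in the cell cycle under CDK4 and CDK6 inhibition. Here the share of cells with cell cycle mRNA was read only at harvest on postnatal day 16, after the last of 5 daily doses begun on day 10. Inhibition at harvest was not measured, and untreated tumours are not analysed here. The share therefore cannot tell which cells stayed in cycle under the drug. Among lineage cells of at least 500 UMIs, thinned to 500, 93.7% ± 6.10 (SD, n = 3) held at least 3 UMIs of the S and G2/M phase genes, but so did 7 of 10 cells called myeloid. At that depth the criterion did not separate cycling from background. In 1938 cells of at least 200 UMIs, thinned to 200, the same number of cycle UMIs was found in 56.3% ± 4.09 of lineage cells (SD, n = 3) and in 2 of 21 cells called myeloid, but also in 17 of 33 called astrocytes and 3 of 3 called erythroid, so it did not separate the lineage from all other cells. Progenitor-like cells reached 60.8% ± 3.02 and granule-neuron-like cells 28.0% ± 1.82 (SD, n = 3 each), so the classes differed by more than the spread between tumours. A UMI of the proliferation genes Mki67 or Top2a was found in 30.7% ± 3.30 of progenitor-like and 10.7% ± 3.099 of granule-neuron-like cells (SD, n = 3 each), against 4 of 21 cells called myeloid and 7 of 33 called astrocytes, too few cells to set a background level for these genes. Free RNA limits these shares, since cycle genes took 1.59%, 1.64% and 1.83% of counts in barcodes of 50 to 99 counts in tumours 1, 2 and 3. At such levels free RNA alone could bring a cell of 200 UMIs to 3 cycle UMIs. Lineage cells averaged 3.389, 4.145 and 4.033 cycle UMIs of 200, near the criterion. The 56.3% is therefore not a share of cycling cells. Also, 448 of 1582 lineage cells lay at or 1 UMI under the criterion.

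**Figure D1:**
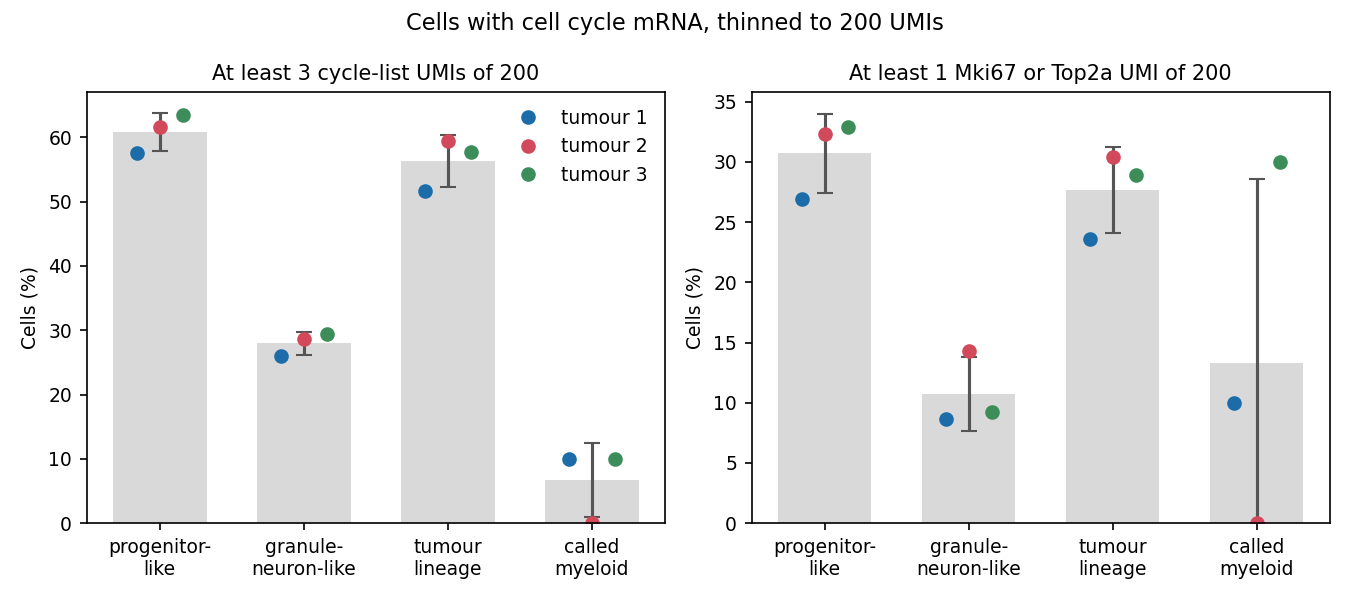
Share of cells (%) with at least 3 cycle-list UMIs (left) and with a Mki67 or Top2a UMI (right), in cells thinned to 200 UMIs, by class. Points are tumours, bars their means and error bars the SD over 3 tumours; progenitor-like cells averaged 60.8% on the left and granule-neuron-like cells 28.0%, and the myeloid bars rest on 21 cells in all.

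What distinguishes lineage cells rich in cell cycle mRNA was asked by dividing those of each tumour into 3 sets of near-equal size by cycle UMIs and comparing the highest set, cycle-high, with the lowest, cycle-low. Granule-neuron-like clusters gave 6.51%, 8.70% and 3.70% of cycle-high against 35.2%, 21.7% and 29.2% of cycle-low cells in tumours 1, 2 and 3, so the sets differ in class as well as in cycle mRNA. With progenitor-like cells alone, 30 genes rose and 8 fell, against 75 and 82 in the whole lineage. Among the rises in all 3 tumours were several genes of mitosis. The splitting list also holds genes of mitosis, so these rises largely restate the ranking. Aspm, which organises spindle poles, was higher by 3.54 on the log2 scale (SE 0.52, edgeR Benjamini-Hochberg adjusted p = 1.762e-09), and the kinetochore scaffold gene Casc5 by 3.27 (SE 0.36, adjusted p = 7.595e-17). Incenp, of the chromosomal passenger complex, was higher by 2.93 (SE 0.36, adjusted p = 5.295e-13), and the centromere gene Sgol2 by 2.94, each in 3 of 3 tumours. Spag5, a spindle protein gene, had 36 counts in the cycle-high and 0 in the cycle-low set, at least 10.35-fold higher against a floor of 3 counts over the group (lower 95% counting limit 7.99-fold). Prr11 had 28 counts against 0, at least 8.05-fold higher (lower limit 6.13-fold). Kif4 and Kif18a, mitotic kinesin genes, were 14.67-fold (95% counting interval 3.76 to 126) and 14.23-fold higher (3.64 to 122), and the centromere gene Cenph 13.52-fold (4.35 to 67.9).

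Neuronal genes were lower in the cycle-high set, which held fewer granule-neuron-like cells. Neurod1 was lower by a log2 change of -1.66 (SE 0.13, edgeR Benjamini-Hochberg adjusted p = 2.9e-31) and the axonal adhesion gene Cntn2 by -2.14 (SE 0.28, adjusted p = 1.664e-11), both in 3 of 3 tumours by CPM. Tumour 2 adds little to this. Its counts in cycle-high and cycle-low cells were 14 and 14 for Neurod1 and 2 and 3 for Cntn2. Apc2, a neuronal regulator of microtubules, was 16.61-fold lower (95% counting interval 5.32 to 83.7), Lzts1 9.66-fold lower (2.95 to 49.98) and Sez6l2 9.85-fold lower (2.34 to 87.9). Further large falls were in Arpp21 (-2.93), the postsynaptic scaffold gene Dlgap4 (-2.73), the calcium-dependent kinase gene Camk2d (-2.61), Clvs1 (-2.57), the potassium channel gene Kcnk1 (-2.49), the glutamate receptor gene Grin2b (-2.48) and Meg3 (-2.41). In progenitor-like cells alone Neurod1 (-1.04, adjusted p = 0.0002164) and Cntn2 (-1.40, 0.02062) still passed, while Meg3 (-1.67, 0.2481) and Kcnk1 (-1.72, 0.221) did not. That class still held clusters of 104 and 48 cells with more granule neuron than progenitor marker counts, so class mixture was not removed there. In all, 75 of 2153 genes rose and 82 fell. The number of genes called depended on tumours 1 and 3, as it was 11 without tumour 1, 141 without tumour 2 and 18 without tumour 3, against 157 with all 3. DESeq2 called 20 genes.

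**Figure D2:**
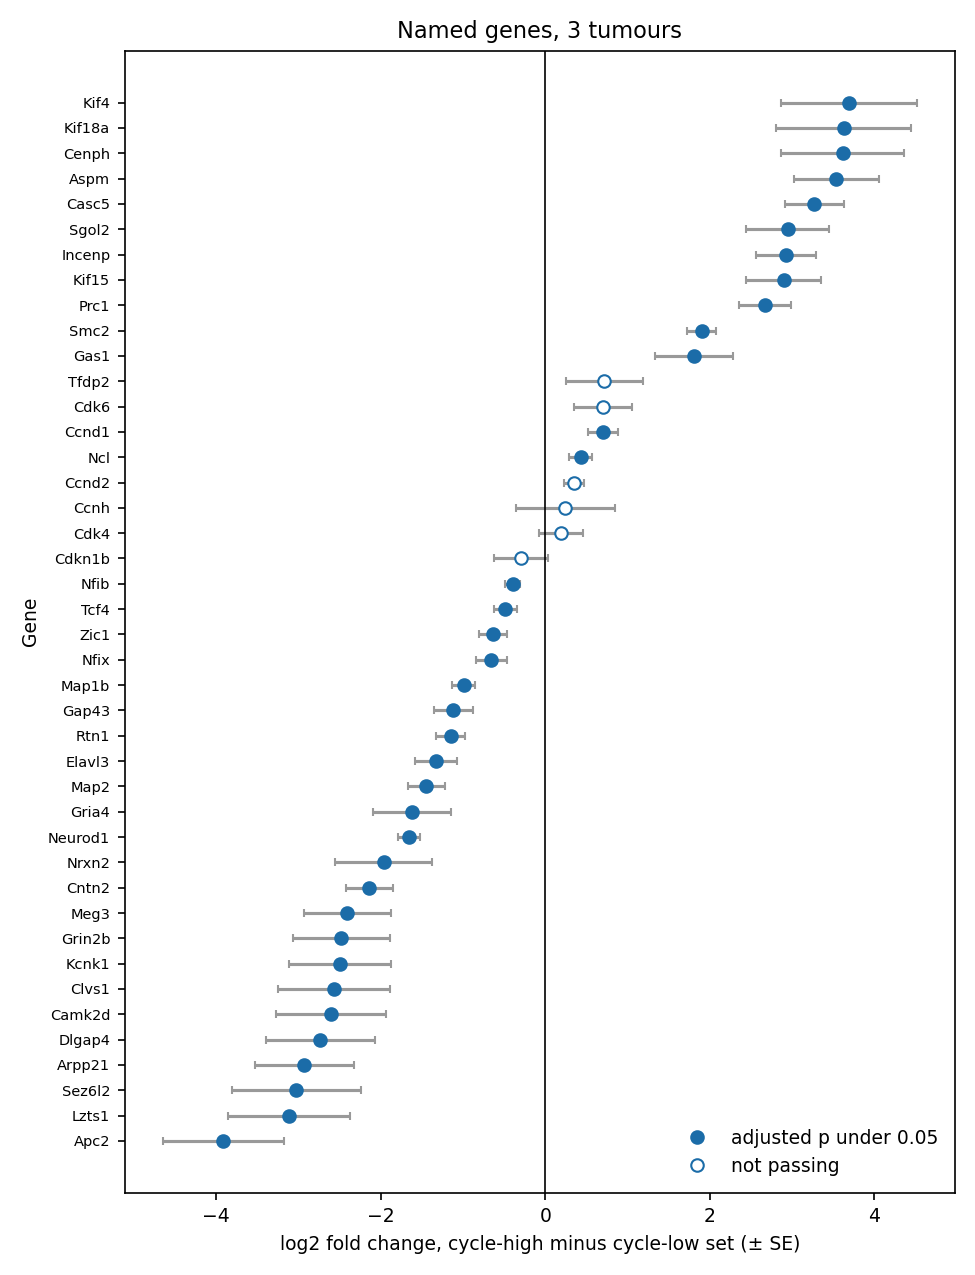
Log2 fold change of the named genes between the cycle-high and cycle-low sets of lineage cells (horizontal axis, error bars SE from edgeR, 3 tumours), without Spag5 and Prr11, which had 0 counts in the cycle-low set. Filled points passed an adjusted p of 0.05, from Kif4 at 3.70 to Apc2 at -3.91.

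By gene list, DNA replication and mitosis genes outside the splitting list rose together. They act in the same cell cycle phases as the splitting genes, so their rise largely restates the ranking and is not separate support. Of 40 measured, 24 rose, 0 fell and 16 did not pass, and 31 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.45e-16; adjusted p = 0.252 with an estimated correlation). They included the condensin gene Smc2 (1.90), the midzone gene Prc1 (2.67) and the kinesin gene Kif15 (2.90). Axon growth and migration genes fell, 15 of 25 with 0 higher and 10 not passing, or 18 lower and 1 higher when adjusted over the list alone (adjusted p = 8.17e-08; 0.252 with an estimated correlation). Among them were the microtubule-associated genes Map1b (-0.99) and Map2 (-1.45), Rtn1 (-1.15) and the RNA-binding gene Elavl3 (-1.33). In progenitor-like cells alone, where lists were not tested, Elavl3 still passed (-1.45, adjusted p = 0.004757), and Map1b (-0.17, 0.8974), Map2 (-0.96, 0.06573), Rtn1 (-0.72, 0.1061), Gap43 (-0.75, 0.3057), Gria4 (-1.69, 0.2165) and Gas1 (1.37, 0.1602) did not, while Smc2 (1.77), Prc1 (2.41) and Kif15 (2.32) did. Class mixture was not removed in that class, as said above for Neurod1. Granule neuron markers fell in 7 of 8 and neuronal state genes, including the growth cone gene Gap43 (-1.12), in 8 of 10, with the same counts when adjusted over the list alone (adjusted p = 3.24e-05 and 0.000136, or 0.252 each with an estimated correlation). These lists share most of their genes, among them Neurod1, Cntn2, Meg3 and Grin2b, so they are not separate lines of support. Synaptic genes fell in 3 of 9, or 5 when adjusted over the list alone (adjusted p = 0.000799; 0.647 with an estimated correlation). They included Nrxn2 (-1.97), which encodes a presynaptic adhesion protein, and the AMPA receptor gene Gria4 (-1.62). DESeq2 called 7 of the 40 replication and mitosis genes, 1 of the 25 axon genes and 2 of the 8 granule neuron markers. It also called 2 of the 10 neuronal state genes and 0 of the 9 synaptic genes, with 3 of these 9 at an unadjusted p under 0.05. Of 4 measured genes of the Hedgehog list, which holds receptor genes as well as targets, the co-receptor gene Gas1 rose (1.81, edgeR adjusted p = 0.004491) and 3 did not pass. A rise of a co-receptor gene does not show higher Hedgehog output. The list passed camera with the preset correlation (adjusted p = 0.0473) but not with an estimated one (0.541).

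Of 7 measured genes of the CDK4 and CDK6 pathway, 1 rose between these sets. Ccnd1, which encodes the cyclin D1 partner of both kinases, rose by 0.70 (SE 0.18, edgeR Benjamini-Hochberg adjusted p = 0.003836) and was higher in 2 of 3 tumours, but it did not pass in progenitor-like cells alone (0.22, 0.8186). Ccnd2 (0.35, adjusted p = 0.06726), Cdk6 (0.71, 0.2948), Tfdp2 (0.72, 0.5084), the inhibitor gene Cdkn1b (-0.29, 0.7911), Cdk4 (0.19, 0.8406) and Ccnh (0.24, 0.9301) did not pass. With adjustment over the list alone, 2 of 7 pathway genes rose. Of 17 genes of the progenitor identity list 5 fell, or 6 when adjusted over the list alone, though the list did not pass (camera, adjusted p = 0.142). They included the transcription factor genes Nfib (-0.39), Nfix (-0.66), Zic1 (-0.64) and Tcf4 (-0.48). Between the neuronal sets described below, Nfib (0.58), Nfix (0.81) and Zic1 (0.58) rose with neuronal mRNA. Their falls here therefore do not show a loss of progenitor identity. In progenitor-like cells alone Nfib (-0.21, 0.5071), Nfix (-0.49, 0.4308), Zic1 (-0.51, 0.221), Tcf4 (-0.38, 0.352) and Ncl (0.30, 0.5096) did not pass. The nucleolar gene Ncl was the only 1 of 32 MYC targets to rise (0.43, adjusted p = 0.03169), in 2 of 3 tumours, and with adjustment over the list alone 0 did in edgeR, with 9 at an unadjusted p under 0.05. Of 7 genes of the mTOR pathway, the target of the drug sapanisertib that the study combined with palbociclib, 0 passed in edgeR, over all genes or when adjusted over the list alone, with 2 at an unadjusted p under 0.05, and 0 passed in DESeq2 or limma-voom. The list did not pass either (camera, adjusted p = 0.693). Of 48 ribosomal protein genes 0 passed in edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 in each, and of 55 nuclear oxidative phosphorylation genes 0 passed in any of these tools, with 2 at an unadjusted p under 0.05 in edgeR.

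The second comparison asked what distinguishes lineage cells rich in neuronal mRNA, comparing the highest with the lowest of 3 sets of each tumour ranked by neuronal UMIs, neuronal-high and neuronal-low. Granule-neuron-like clusters gave 40.2%, 17.4% and 35.0% of neuronal-high against 8.05%, 4.35% and 3.29% of neuronal-low cells in tumours 1, 2 and 3. The mitochondrial share also differed, at 4.21%, 6.37% and 4.52% in neuronal-high against 5.12%, 6.97% and 5.38% in neuronal-low cells. In the 69 lineage cells of tumour 2 the neuronal UMIs varied by 1.004 times the binomial value, so its sets may be near a random deal and its direction adds little. With a minimum of 100 UMIs its 357 lineage cells gave 1.301 times, against 1.433 and 1.252 in tumours 1 and 3. With progenitor-like cells alone 0 of 1669 genes passed in edgeR, the only tool run there, with 82 at an unadjusted p under 0.05, so the calls made in the whole lineage were not seen within that class. Celf4 rose by 2.11 (SE 0.32, edgeR Benjamini-Hochberg adjusted p = 1.691e-08) in the neuronal-high set, and the growth cone gene Dpysl3 also by 2.11 (SE 0.42, adjusted p = 8.106e-05), each in 3 of 3 tumours. Arpp21 (3.24), Apc2 (2.12), the microtubule gene Map6 (2.05), Trpc4ap (2.04), the chromatin remodeller gene Chd3 (1.94), the neuronal transcription factor gene Myt1 (1.92) and the noncoding A930011O12Rik (2.06) were the other large rises. Gm16183 had 25 counts against 1, 27.06-fold higher (95% counting interval 4.43 to 1111). Among the falls were the helicase gene Mcm6 (-1.56), Atad5, which unloads PCNA (-1.22), and the histone chaperone gene Nasp (-0.83), with the condensin gene Smc2 (-0.77) and the kinetochore gene Cenpf (-0.65). Further falls were in the RNA modification gene Dkc1 (-1.09), the snoRNA host gene Gas5 (-1.03) and the respiratory chain gene Cox6c (-0.92), and Ccm2 was 7.39-fold lower (2.24 to 38.3). Of 2177 genes, 54 rose and 24 fell in edgeR, with 272 at an unadjusted p under 0.05. DESeq2 called 0 genes, with 68 at an unadjusted p under 0.05, and limma-voom called 30. The count was 0 without tumour 1 in edgeR (36 at an unadjusted p under 0.05), 172 without tumour 2 and 1 without tumour 3.

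**Figure D3:**
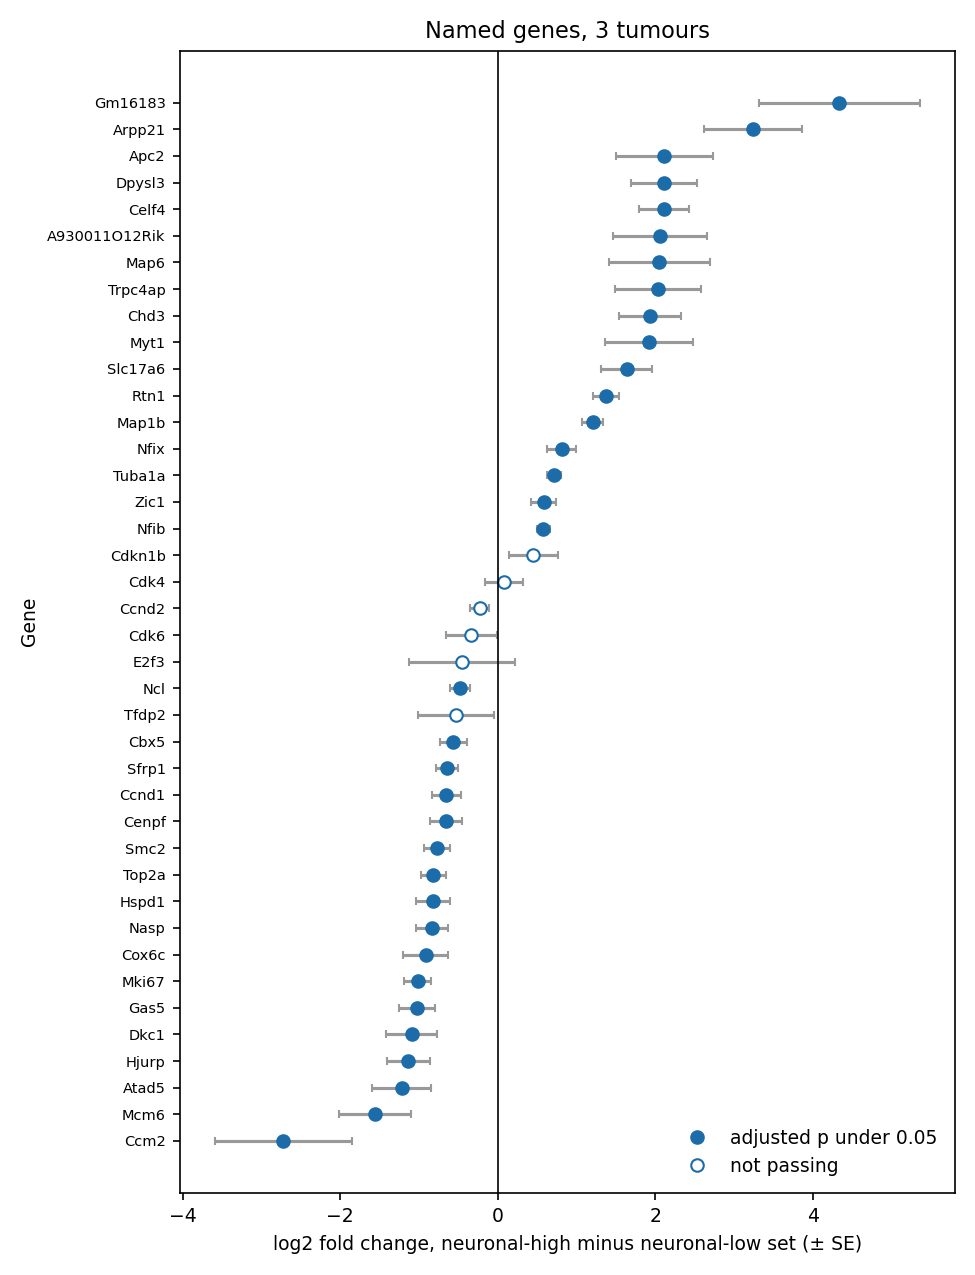
Log2 fold change of the named genes between the neuronal-high and neuronal-low sets of lineage cells (horizontal axis, error bars SE from edgeR, 3 tumours). Filled points passed an adjusted p of 0.05, from Gm16183 at 4.34, with 1 count in the neuronal-low set, to Ccm2 at -2.72.

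Axon growth and migration genes were the only list to pass between the neuronal sets. Like the splitting genes they are neuronal genes, so their rise largely restates the ranking and is not separate support. Of 25 measured, 16 rose, 0 fell and 9 did not pass, and 18 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.41e-08; adjusted p = 0.509 with an estimated correlation). They included Map1b (1.21), Rtn1 (1.38) and the tubulin gene Tuba1a (0.72), whose reads can be shared with near-identical tubulins. Of these 25 axon genes DESeq2 called 0, with 11 at an unadjusted p under 0.05, and limma-voom called 6. Without tumour 2, 7 lists passed, without tumour 3, 2 did, and without tumour 1, 1 did. Of 30 G2/M genes 6 fell, including Mki67 (-1.02), Top2a (-0.82), Hjurp (-1.13) and Cbx5 (-0.56), each lower in 2 of 3 tumours, and 10 fell with 1 higher when adjusted over the list alone (adjusted p = 0.093 for the list). Of 20 S phase genes 2 fell, also when adjusted over the list alone (adjusted p = 0.0514). The Hedgehog target Sfrp1, which encodes a secreted Wnt antagonist, fell by 0.65 on the log2 scale (SE 0.14, edgeR Benjamini-Hochberg adjusted p = 0.0003584) in 3 of 3 tumours. It was the only 1 of 4 measured genes of the Hedgehog list to pass, or 2 did when adjusted over the list alone (list adjusted p = 0.301). Ccnd1 fell by 0.65 (SE 0.18, adjusted p = 0.01356) in 3 of 3 tumours.

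The remaining pathway genes did not pass between the neuronal sets, namely Ccnd2 (-0.23, edgeR Benjamini-Hochberg adjusted p = 0.4053), Cdkn1b (0.45, 0.584), Tfdp2 (-0.53, 0.729), Cdk6 (-0.34, 0.7515), E2f3 (-0.46, 0.8629) and Cdk4 (0.08, 0.9506). Nfib (0.58), Nfix (0.81) and Zic1 (0.58) rose, 3 of 17 genes of the progenitor identity list, or 7 when adjusted over the list alone (camera, adjusted p = 0.105). Of 8 synaptic genes 2 rose, including the vesicular glutamate transporter gene Slc17a6 (1.64, higher in 2 of 3 tumours), or 6 with 1 lower when adjusted over the list alone (adjusted p = 0.121). The MYC targets Dkc1, Hspd1 and Ncl (-0.48) passed as lower, 3 of 31, or 4 when adjusted over the list alone (adjusted p = 0.48). For Hspd1 the fitted change of -0.82 follows tumours 1 and 3, and its mean over tumours did not fall (673.7 CPM in neuronal-high and 670.5 in neuronal-low cells), as tumour 2 had 1108.5 against 160.7. Of 5 mTOR pathway genes 0 passed in edgeR, over all genes or when adjusted over the list alone, with 0 at an unadjusted p under 0.05 there and in DESeq2 and limma-voom (list adjusted p = 0.196). Smc2 was the only 1 of 39 replication and mitosis genes outside the cycle lists to fall, and Cox6c the only 1 of 58 oxidative phosphorylation genes (list adjusted p = 0.121 and 0.976). Of 48 ribosomal protein genes 0 passed in edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05 in edgeR (list adjusted p = 0.0514).

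Levels of the drug's targets and of its transporters were read in the tumour totals, as CPM of non-mitochondrial counts. These totals take in all barcodes. Barcodes of under 200 counts, which may hold free RNA or damaged cells, gave most of their counts. Ccnd2 stood at 2067 ± 209, Ccnd1 at 1113 ± 371, Cdk4 at 586 ± 144, Cdkn1b at 381 ± 44.1 and Cdk6 at 246 ± 95.5 (SD, n = 3 each). Ccnd3 (50.2 ± 16.1), Cdkn1a (57.6 ± 17.4), Rb1 (39.8 ± 21.0), Eif4ebp1 (44.8 ± 7.76), Mtor (10.7 ± 6.79) and Smo (14.6 ± 7.19) were far lower (SD, n = 3 each). Igf2 stood at 96.2 ± 69.9 and Igf1 at 29.0 ± 16.4, and the drug efflux transporter genes Abcb1a at 12.19 ± 13.04 and Abcg2 at 24.2 ± 11.2 (SD, n = 3 each). In pooled cells of at least 200 UMIs, Ccnd1 was 581 CPM in granule-neuron-like cells (exact Poisson 95% interval 455 to 732) and 1213 in progenitor-like cells (1119 to 1314). Ccnd2 was 1533 (1323 to 1767) and 2217 (2088 to 2351) in the same classes. Cells called vascular, 5 of at least 500 UMIs, held 12 counts of the CDK inhibitor gene Cdkn1a, 5 in 3 cells of tumour 1, 7 in 1 cell of tumour 2 and 0 in 1 cell of tumour 3. That is 1627 CPM (841 to 2843), against 25.5 (10.3 to 52.6) in lineage cells. They held 3 counts of Abcb1a, 1 in each tumour, or 407 CPM (83.9 to 1189), against 7.3 (0.9 to 26.3) in lineage cells. Myeloid-like cells held 5 counts of Igf1, of which 3 came from the 1 cell of tumour 2, 2 from 3 cells of tumour 1 and 0 from 7 cells of tumour 3. These intervals cover counting error only, and no test was run between the classes.

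**Figure D4:**
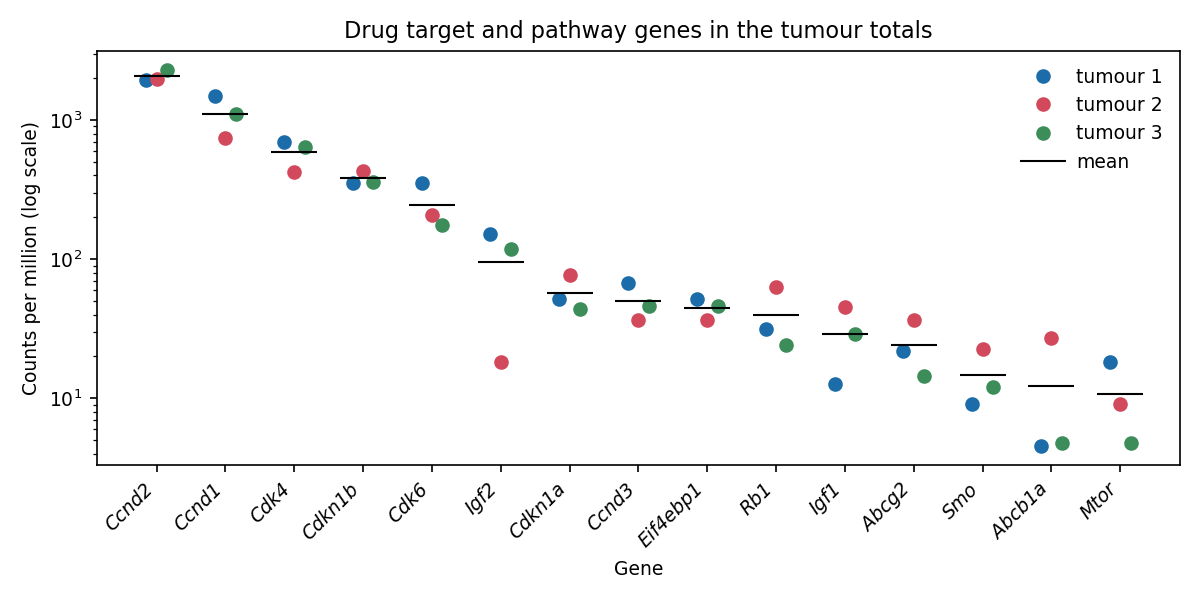
CPM (logarithmic axis) of drug target and pathway genes in the total of all barcodes of each tumour. Points are tumours and the line is the mean of 3. Ccnd2 was highest at a mean of 2067 and Mtor lowest at 10.7.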

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

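The tests of genes called between sets, of free RNA in neuronal genes and of mitochondrial shares were chosen after the results had been seen, and the test of cell cycle mRNA in cells called myeloid was set before its result was seen. With 1 group of tumours, no biological explanation was tested for any pattern.

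Barcodes of under 200 counts are not used in the comparisons, yet they held marker counts of cell types for which 3 or fewer cells were called. By raw counts tumour 3, the tumour with the largest total, held the most in each case. Erythroid markers had 1118 counts in tumour 3, against 341 and 140 in tumours 1 and 2, of which the globin gene Hbb-bs gave 649. Choroid plexus markers had 207 counts in tumour 3, against 30 and 6, of which the transthyretin gene Ttr gave 175. Purkinje cell markers had 127 counts in tumour 3 (96 and 21 in tumours 1 and 2), ependymal markers 63 (58 and 20), GABA interneuron markers 33 (6 and 10) and neutrophil markers 4 (2 and 0). Scaled to all counts in barcodes of under 200 counts, tumour 3 was highest for erythroid (498.4, 692.0 and 1207.4 CPM in tumours 1, 2 and 3), choroid plexus (43.8, 29.7 and 223.6) and neutrophil markers (2.9, 0 and 4.3), but not for ependymal (84.8, 98.9 and 68.0), GABA interneuron (8.8, 49.4 and 35.6) and Purkinje markers (140.3, 103.8 and 137.2). The counts are summed over many shallow barcodes and do not show that cells of these types were present. No control samples are analysed here. Choroid plexus, ependymal, Purkinje and GABA interneuron calls were absent among the 1938 cells of at least 200 UMIs.

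Between the cycle-high and cycle-low sets, 157 genes were called, and between the neuronal sets 78. Only 10 splits of the 6 sums exist, too few for a share under 0.05. In each comparison 1 split, the real one, reached its own count, and the highest other split called 79 and 38 genes. That split exchanges the sums of tumour 2 alone and also parts all 3 pairs. Dealing the same cells to groups at random gave at most 0 calls in 50 deals for the cycle sets and at most 1 call for the neuronal sets in edgeR (on average 46.0 and 51.0 genes at an unadjusted p under 0.05), which argues against sampling noise between cells.

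A higher count total of cycle-high cells does not account for most calls. In cells of tumours 1 and 3 matched on count total, 86.8% of the called genes tested again were called in the same direction. Neuronal mRNA was higher in cycle-low than in cycle-high cells. Free RNA stays open as its source for tumour 2, where the neuronal share in cycle-low cells was 1.002 times that in barcodes of under 100 counts. In tumours 1 and 3 it was at least 1.394 times, with the 95% interval above the level of those barcodes, which argues against free RNA as the whole source there. Those barcodes may hold damaged cells as well as free RNA.

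Tumour 2 held 11.4% mitochondrial counts, against 3.97% in tumour 1 and 5.61% in tumour 3, mostly from the ribosomal RNA gene mt-Rnr2. A few extreme barcodes do not account for it, since the median share in barcodes of under 200 counts was 2.32 times that of the higher of the other tumours. Lower depth does not either, since the share was 2.05 times as high in barcodes of at least 100 and under 200 counts. Damaged cells that lost cytoplasmic RNA could give it, as the nuclear RNA Malat1 was 2.4 times as high in those barcodes. Mitochondrial mRNA was only 1.38 times as high, though, and this leaves damage and a difference in library preparation open.

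Cells called myeloid held cell cycle mRNA, 59 cycle-list counts beside 32 counts of tumour lineage markers. Cycle counts were 64.84% of both together (exact 95% interval 54.1 to 74.6), against 67.4% in barcodes of under 100 counts. Free RNA or second cells from the tumour lineage may therefore be the source, and the values give no sign of cycling myeloid cells beyond it. Cells called astrocytes had 72.9% (69.0 to 76.6) against 67.1% in the same barcodes. Cells called oligodendrocyte lineage had 74.0% (66.1 to 80.9) against 67.0%. The astrocyte interval lies above the barcodes, but it treats counts of the same cell as independent. Between lineage cells, cycle UMIs varied by 2.686, 3.603 and 3.132 times the binomial value in tumours 1, 2 and 3. An excess in astrocytes is therefore not established.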

How the results depend on the processing

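The alternatives for cell shares at 500 UMIs were planned before the data were examined; those for the sets, the 200-UMI shares, the marker calls and the list tests were chosen after seeing the data. The planned tests between states and classes, their list tests and their alternatives, including cells of at least 1000 UMIs thinned to 1000, were not run. No tumour had enough cells in both states of a comparison. The class tests needed enough cells in every tumour, and the tumour with the fewest cells fell short. Unless stated, the cause of a change was not tested.

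At 500 UMIs the lineage share fell to 46.8% with a minimum of 1000 UMIs, where the mixed class took 53.2% and 29, 2 and 18 cells were left in tumours 1, 2 and 3. The mixed share was 24.2% with a mitochondrial limit of 5%. Granule-neuron-like cells made up 37.7% at resolution 0.5 and 12.3% with cycle and drug genes kept in clustering. The lineage's cycling share was 83.6% with a criterion of 5 UMIs. At 200 UMIs it was 51.3% with a limit of 5%. The granule-neuron-like cycling share was 31.5% with doublets kept, 31.9% with a limit of 20% and 33.8% at resolution 0.5. The myeloid call share was 0.763% with a limit of 5% and 2.13% with 20%. With each tumour left out, the lineage share ranged from 76.8% to 94.5%, and the lineage's cycling share from 90.5% to 96.6% at 500 UMIs and from 54.7% to 58.6% at 200 UMIs.

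For the cycle sets, the 157 calls became 20 with DESeq2, 89 with no filter on low counts, 12 with at least 10 counts in every sum (21 genes tested), 62 with no replicate block and 11 to 141 with each tumour left out. They became 95 with a mitochondrial limit of 5%, 78 at resolution 1.5, 78 in sums of thinned cells, and 66, 55 and 45 with minimums of 300, 500 and 100 UMIs. In progenitor-like cells alone they became 38. The limit of 5%, resolution 1.5 and the minimums of 300 and 500 UMIs also lost tumour 2, whose loss by itself gave 141, so the setting and the loss of a tumour are not separated. The other 10 settings stayed within 1.5 times. For the neuronal sets, the 78 calls became 0 with DESeq2 (68 at an unadjusted p under 0.05), 30 with limma-voom, 42 with no filter, 7 with at least 10 counts in every sum, 8 with no replicate block and 0 to 172 with each tumour left out. They became 124 with a limit of 5%, 164 at resolution 1.5, 48 in thinned sums, 136 when split on unthinned shares, and 183, 16 and 20 with minimums of 300, 500 and 100 UMIs, and 0 in progenitor-like cells alone in edgeR (82 at an unadjusted p under 0.05). The limit of 5%, resolution 1.5 and the minimums of 300 and 500 UMIs again lost tumour 2, and leaving out tumour 2 by itself gave 172. No called gene was called in the opposite direction under any setting. Of the 6 lists called between cycle sets, 0 were with an estimated correlation and 2 with fry (6 to 7 with each tumour left out). The granule neuron and neuronal state lists among them share most of their genes. Between neuronal sets, where 1 was called, 0 were with an estimated correlation, 0 with fry, 10 on voom values, 1 to 7 with each tumour left out, 10 and 6 with minimums of 100 and 500 UMIs, and 7 when matched on UMI total. The minimum of 500 and the matching rest on tumours 1 and 3, and leaving out tumour 2 by itself also gave 7.

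Named called genes were not reversed by any setting: 633 of 820 values kept their side of the threshold and 187 lost it for the cycle sets, and 462 of 777 kept and 315 lost it for the neuronal sets. Over all genes called between cycle sets, 152 of 154 tested again kept their direction with a minimum of 100 UMIs and 126 of 127 in progenitor-like cells alone, and under the other settings all did. Named genes that reversed had not passed. Between cycle sets, Tfdp2 was -0.10 and -0.46 with minimums of 300 and 100 UMIs. Cdkn1b was 0.045 without tumour 1 (range -0.414 to 0.045 with each tumour left out), 0.092 with doublets kept, 0.07 with a limit of 20%, 0.072 when split at the median and 0.26 with a minimum of 500. Cdk4 was -0.46 and -0.039 with limits of 5% and 20%, -0.087 when matched and -0.003 in thinned sums. Ccnh was -0.063 when split on unthinned shares. Between neuronal sets, Ccnd2 was 0.002 and Cdk6 0.093 in progenitor-like cells alone. Cdkn1b ranged from -0.116 to 0.541 with each tumour left out, the lowest without tumour 3. Tfdp2 was 0.047 with doublets kept, 0.005 with a limit of 20% and 0.72 with a minimum of 300. E2f3 was 0.29 with doublets kept and 0.006 at resolution 0.5 and by marker calls. Cdk4 was -0.33 with a limit of 5%, -0.015 at resolution 0.5 and by marker calls, -0.093 at resolution 1.5, -0.076 when split at the median and -0.019 with a minimum of 300. Depth limits both comparisons, as tumour 2 gave 23 cells per set.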

Other observations

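Cycle genes took 1.59% of non-mitochondrial counts in barcodes of 50 to 99 counts and 2.13% in those of 500 or more in tumour 1, 1.64% and 1.60% in tumour 2, and 1.83% and 2.55% in tumour 3. Neuronal state genes took 0.543% and 0.394% in tumour 1, 0.767% and 0.373% in tumour 2, and 0.597% and 0.390% in tumour 3. In lineage cells thinned to 200 UMIs, the variance of cycle UMIs between cells was 2.69, 3.60 and 3.13 times the binomial value in tumours 1, 2 and 3. For neuronal UMIs it was 1.957, 1.004 and 1.901 times. The neuronal ranking of the 69 cells of tumour 2 thus showed no more spread between cells than counting gives. With a minimum of 100 UMIs its 357 lineage cells gave 1.301 times the binomial value.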
